A study of Mus musculus with 12 samples.

How the data were processed

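RNA of sorted mouse bone marrow cells was measured on 12 Affymetrix gene arrays, 3 for each of 4 groups. Per the labels, 20 ng of total RNA per sample was amplified, and 2.5 µg of the amplified cDNA was fragmented and labelled with biotin. The deposited values are on a log2 scale, as their range from 0.94 to 13.4 shows, and the submitters' processing notes name RMA and the affy package without a version. RMA subtracts background, gives arrays a common distribution and summarises the probes of each probe set, so differences are relative to the bulk of probe sets, and folds of dim genes are compressed. Whether the 12 arrays were normalised together is not given in the sources used here. Over all probe sets the array medians lay between 5.41 and 5.54. The interquartile ranges were less alike, between 2.83 and 2.99 in HSC arrays and between 2.50 and 2.84 in MPP arrays. Comparisons across the populations carry this difference in spread. Arrays carry no read depth. Their number, 3 per group, limits the precision.

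The value table holds 18719 probe sets. The probe annotation used here gives 10657 of them 1 gene symbol and 523 several, and 7539 are not listed in it and stay unnamed. Whether those 7539 measure transcripts or are array controls is not known from it. Each gene was represented by the probe set with the highest mean over all arrays, among those with 1 symbol, which left 9984 genes, 364 of them with more than 1 probe set. Erg, the targeted gene, is not analysed here, nor are Myc, Slamf1, Cd48, Kit, Ly6a and Cd34. Neighbours of Erg were taken from the RefSeq gene table of assembly GRCm38.p6, in which 9934 gene IDs matched and 51 did not. The build behind the array annotation is not given in the sources used here, so no coordinates are printed.

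Groups were taken from the genotype labels, which give Erg +/- for the HSC samples whose titles call them knock-outs. All comparisons came from 1 limma model (limma 3.58.1, R 4.3.3) with a mean per group over the 12 arrays, which leaves 8 residual degrees of freedom plus 4.35 from the empirical Bayes prior, and no filter on dim probe sets. Tests were two-sided, and p-values were adjusted over the 9984 genes by Benjamini-Hochberg with a threshold of 0.05. Fold changes are 2 to the power of the log2 difference, and SE is the moderated standard error. The labels do not state that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

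A set of 24 gene lists was fixed before the data were examined, with 477 distinct genes, of which 184 have a value. The 22 lists with at least 4 measured members were tested with camera at its preset correlation of 0.01, adjusted over the lists within each comparison. The list of stem cell transcription factors has 0 measured members and that of sorting markers has 1, so neither was tested. Camera with an estimated correlation and fry were run as alternatives. Named genes follow a rule fixed at the same time. It takes, per comparison and direction, the 10 largest changes among called genes whose groups do not overlap (5 for the difference of effects and for the controls, without the overlap condition for the difference), or, where fewer than 5 pass, the 5 smallest p-values. From each list it takes up to 4 called members, or up to 2 with the smallest p where none is called. Predicted genes, clones, small RNAs and sensory receptors were counted and not named. Further members of called lists were named after their values were seen.

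The fit was tested on simulated data after the first results had been seen, with normal noise for the 9984 genes at their observed means and moderated spread. For the HSC comparison 54 of 100 genes changed by 1 log2 unit and 96 of 100 changed by 2 units were called, with 11 unchanged genes called. For the MPP comparison 60 and 98 of 100 were called, with 6 unchanged genes called. Lists of 10 genes shifted by 0.5 log2 units were called in 20 of 20 cases in each comparison, and 0 of 20 unshifted lists were called. The simulated noise was independent between genes, whereas the estimated correlation within the real lists reached 0.362, for B cell markers. The simulation therefore cannot show how often lists of correlated genes are called falsely.

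Alternatives were a replicate block, filters at the 25th and 50th percentile of mean value, the mean of a gene's probe sets, a repeated quantile normalisation, median centring, an intensity trend with robust moderation, array weights, only the arrays compared, all deposited probe sets, and each array left out in turn. Leaving out the 2 arrays of lowest weight together, Erg +/+ HSC replicate 1 and Erg fl/fl MPP replicate 1, was chosen after seeing the data. Other windows around Erg and a stricter overlap threshold were also tried.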

Results

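Gene expression was profiled in 2 stem and progenitor populations of male mice with reduced or absent Erg, an ETS-family transcription factor of blood stem cells. Hematopoietic stem cells (HSCs), sorted from c-Kit-enriched marrow as Lineage-negative, Sca-1-positive, c-Kit-positive, CD150-positive and CD48-negative, came from Erg +/+ and from Erg +/- mice, with 3 arrays each. Multipotent progenitors (MPPs) came from Erg fl/fl mice without Cre and from Erg -/- mice, in which Mx1-Cre removed the floxed exon 11, with 3 arrays each. The titles of the Erg +/- samples call them knock-outs, and the comparison follows the genotype field and the description of a deleter Cre cross, which both give Erg +/-. Per the labels, both MPP groups had received 5 injections of pIpC, a double-stranded RNA that induces interferon and with it Mx1-Cre, and were sorted 2 weeks after the first. The MPP labels disagree on the gate: the sorting field gives CD150-negative cells, whereas the source field repeats the CD150-positive, CD48-negative gate of the HSCs. Arrays of a group correlated at r = 0.9528 to 0.9743 across the 9984 genes. The targeted gene is not analysed here, so the genotype labels were not checked on Erg itself.

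The first comparison asked what the loss of 1 Erg allele does in HSCs. Cracd, which encodes a regulator of actin capping, rose 3.08-fold in Erg +/- HSCs, from a log2 value of 6.14 ± 0.0419 to 7.77 ± 0.131 (SD, n = 3 each). Sparc, which encodes a collagen-binding matrix protein, fell 4.23-fold, from 7.59 ± 0.327 to 5.51 ± 0.408. As a group, the endothelial and stromal markers were lower in Erg +/- HSCs. For both genes the 3 arrays of one genotype lay wholly apart from the 3 of the other.

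These were the 2 genes of 9984 that passed the threshold in HSCs, by limma with adjusted p = 0.00303 for Cracd (probe set 10522655, SE 0.164) and 0.0401 for Sparc (SE 0.285). Neither passed with the replicate block (adjusted p = 0.0732 and 0.0935), with only the HSC arrays (0.0975 and 0.206) or without Erg +/+ replicate 1 and Erg fl/fl replicate 1 together (0.0739 and 0.156), and over all probe sets Cracd passed and Sparc did not (0.023 and 0.119). At an unadjusted p under 0.05 there were 631 genes, 273 higher and 358 lower, where 499 would be expected by chance. The next smallest p-values among genes higher in Erg +/- HSCs belonged to Nupr1, a stress-responsive transcriptional regulator, at 1.22 log2 units, P2ry10, a G protein-coupled receptor, at 1.75, Ces2g at 1.07 and Ly9, a SLAM-family receptor, at 1.01, with adjusted p from 0.0507 to 0.0958. Among lower genes they belonged to Slc29a3, a nucleoside transporter, at -1.01 log2 units, Efna1, an ephrin ligand, at -1.87, Arhgap10 at -1.14 and Stimate at -1.18, with adjusted p from 0.0625 to 0.119. Flt3, the receptor tyrosine kinase of lymphoid-primed progenitors, stood at -1.33 log2 units in Erg +/- HSCs with adjusted p = 0.119, and so did not pass over all genes. It did when adjusted over the early lymphoid list alone (adjusted p = 0.00117, and 0.000124 to 0.00796 with 1 array left out), a list that did not pass itself. The interferon-induced gene Oasl1, at 0.62 log2 units, passed over its list alone (adjusted p = 0.0442), but with 1 array left out only without Erg +/+ replicate 3 (otherwise up to 0.197). A second probe set of Cracd differed by 0.34 log2 units (unadjusted p = 0.18 by limma), and with means of probe sets Cracd (0.98 log2 units, adjusted p = 0.089) and Sparc (0.0593) missed the threshold. Without any 1 of 4 of the 6 HSC arrays (Erg +/+ replicates 1 and 3, Erg +/- replicates 1 and 3) Sparc missed the threshold and 1 gene was called, against 8 genes without Erg +/+ replicate 2 and 6 without Erg +/- replicate 2.

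**Figure D1:**
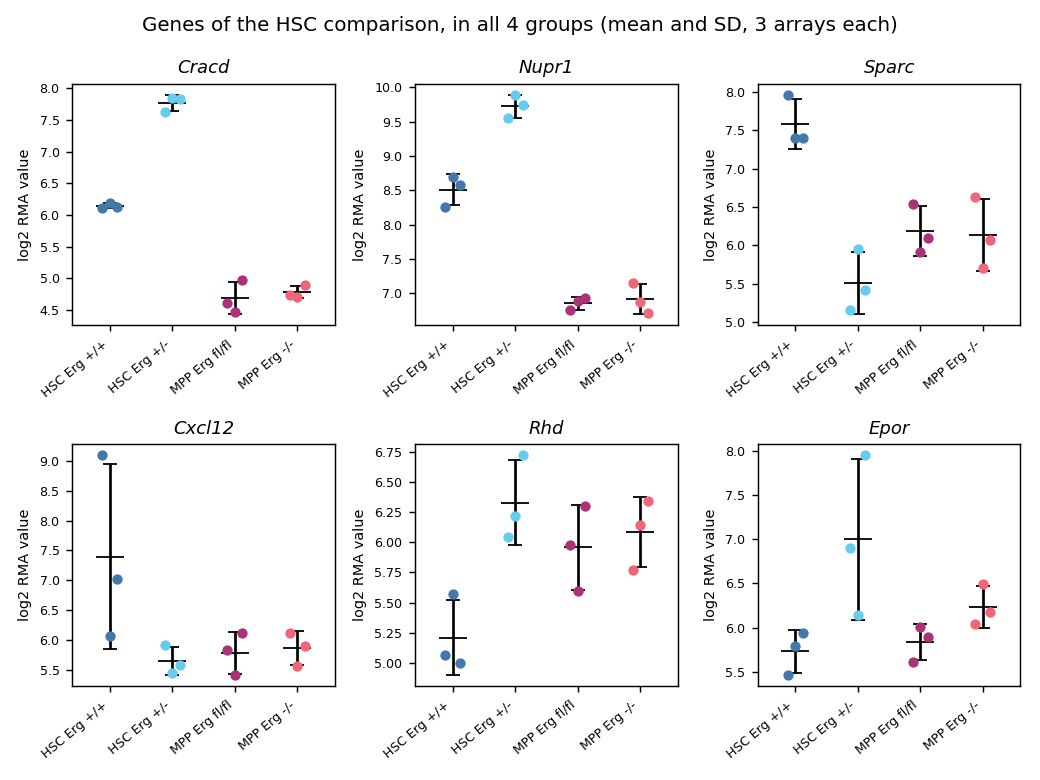
Log2 RMA values (vertical axis) of 6 genes in the 4 groups (horizontal axis), with points for arrays and bars for the mean and SD of 3 arrays. Cracd is higher and Sparc lower in Erg +/- than in Erg +/+ HSCs, with means of 7.77 against 6.14 and of 5.51 against 7.59. Cxcl12 reaches 9.09 in a single Erg +/+ array.

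All 11 measured erythroid genes had positive differences in Erg +/- HSCs, with a mean of 0.637 log2 units (camera, adjusted p = 7.31e-06), a call that was lost with an estimated correlation (adjusted p = 0.0827 with an estimated correlation). Adjusted over the list alone, 2 rose, the erythropoietin receptor gene Epor at 1.27 log2 units and the Rh antigen gene Rhd at 1.12, and neither passed over all genes. Epor missed that threshold without Erg +/+ replicate 1 (0.0619 over the list alone), and was at 0.79 log2 units without Erg +/- replicate 3 (0.0377). All 7 measured endothelial and stromal markers had negative differences, with a mean of -0.816 (adjusted p = 7.31e-06, and adjusted p = 0.0171 with an estimated correlation). Adjusted over the list alone 3 fell, Sparc, the stromal chemokine gene Cxcl12 at -1.75 log2 units and the mural cell receptor gene Pdgfrb at -0.67, and of these Sparc passed over all genes. The size of the Cxcl12 difference depends on Erg +/+ replicate 1, without which it was -0.90 log2 units and still passed over the list alone (0.0299), but it missed the threshold without Erg +/- replicate 2 (0.055), and Pdgfrb without Erg +/+ replicate 1 or 3 or Erg +/- replicate 1 or 2 (0.0932 to 0.167). Of the 22 Myc-associated ribosome biogenesis and growth genes 18 had positive differences, with a mean of 0.209 (adjusted p = 0.00384), 0 of them called over all genes or adjusted over the list alone, and that call was lost with an estimated correlation (adjusted p = 0.595), with fry (adjusted p = 0.389) and without Erg +/+ replicate 2, Erg +/+ replicate 3 or Erg +/- replicate 3 (adjusted p = 0.0572, 0.069 and 0.0801). Of the 6 measured HSC-associated genes 1, Nupr1, rose when adjusted over the list alone, and the list did not pass (adjusted p = 0.685). Of the 6 measured ETS-family genes, Etv5 at 0.70 and Ets1 at -0.60 log2 units passed when adjusted over the list alone, though not without Erg +/+ replicate 3 or Erg +/- replicate 3 (0.0696 and 0.0838), and 0 passed over all genes. The other 19 lists did not pass, with adjusted p of 0.0536 or more. Among these, median, mean and camera direction differed in sign for 3.

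The second comparison asked what the loss of both Erg alleles does in MPPs. Its groups also differ in Mx1-Cre, which the Erg fl/fl mice lacked, so genotype and Cre cannot be separated. In Erg -/- MPPs 8 genes fell and 0 rose. The genes of the surrogate light chain of the pre-B cell receptor were among them: Vpreb1 fell 26.9-fold, from 10.11 ± 0.485 to 5.36 ± 0.0437 (SD, n = 3 each), and Igll1 fell 3.69-fold. Mcpt8, a basophil serine protease, fell 11.6-fold, Nkg7, a protein of cytotoxic granules, 8.27-fold, and Serpinb1a, an inhibitor of neutrophil proteases, 5.78-fold. Ifitm1, an interferon-inducible membrane protein, fell 3.16-fold, AW112010 3.89-fold, and Fxyd5, a modulator of the sodium pump, 2.33-fold.

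For all 8 genes the 3 Erg -/- arrays lay below the 3 Erg fl/fl arrays. By limma, adjusted p was 0.000442 for Igll1 (SE 0.173), Ifitm1 (SE 0.155) and AW112010 (SE 0.183), 0.0029 for Mcpt8 (SE 0.403), 0.00326 for Vpreb1 (SE 0.559), 0.0124 for Fxyd5 (SE 0.166) and 0.0274 for Nkg7 (SE 0.459) and Serpinb1a (SE 0.384). A second probe set of Ifitm1 fell by 2.00 on the log2 scale. Over all probe sets 6 were called in MPPs, all lower, with both probe sets of Ifitm1 among them (limma, adjusted p = 0.00369 for each). Some of the 8 genes therefore did not pass there. At an unadjusted p under 0.05 there were 478 genes, 121 higher and 357 lower, where 499 would be expected by chance. The smallest p-values among higher genes belonged to Ttc39b at 1.52 log2 units, the noncoding RNA Airn at 1.96, the ETS factor Etv5 at 0.90, Bank1 at 1.26 and Ublcp1 at 2.83, with adjusted p from 0.0892 to 0.455. Vpreb1, Mcpt8, Igll1, Ifitm1 and AW112010 stayed called whichever MPP array was left out, Nkg7 and Serpinb1a were lost in each of the 6 cases (highest adjusted p = 0.219) and Fxyd5 in 5 (highest adjusted p = 0.0838). Fxyd5 also missed the threshold with the replicate block and with only the MPP arrays (adjusted p = 0.0801 and 0.102). Without Erg fl/fl replicate 1 and Erg +/+ HSC replicate 1 together, 4 genes were called, and Mcpt8 missed the threshold (adjusted p = 0.0512).

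**Figure D2:**
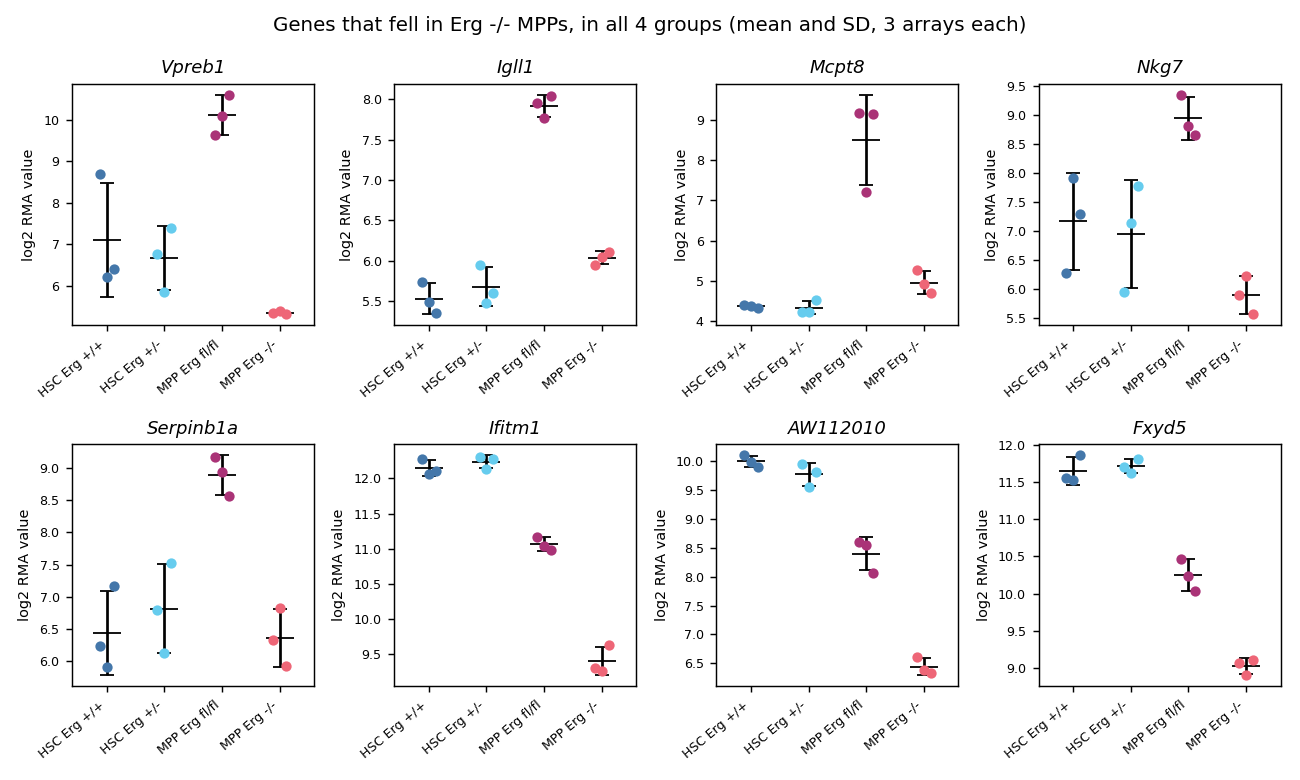
Log2 RMA values (vertical axis) of the 8 genes that fell in Erg -/- MPPs, in the 4 groups (horizontal axis), with points for arrays and bars for the mean and SD of 3 arrays. Ifitm1, AW112010 and Fxyd5 are lower in Erg -/- MPPs than in every other group, with means of 9.40, 6.44 and 9.03.

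The B cell markers were lower as a group in Erg -/- MPPs, with a mean of -1.5 log2 units over 5 measured genes (camera, adjusted p = 1.09e-06, and adjusted p = 0.132 with an estimated correlation). Vpreb1 and Igll1 fell, over all genes as well as adjusted over the list alone, whereas Cd79a, a pre-B cell receptor signalling chain, stood at -0.74, the B-lineage factor gene Pax5 at -0.20 and Cd24a at 0.05. Of the 4 measured mast cell and basophil markers Mcpt8 fell, and Ms4a2 at -0.64, Hdc at -0.37 and Il6ra at 0.09 did not pass (list adjusted p = 0.00124, and adjusted p = 0.132 with an estimated correlation). Of the 9 measured granulocyte-macrophage progenitor genes Nkg7 and, adjusted over the list alone, the protease inhibitor gene Cst7 at -1.65 fell, and 5 had negative differences (list adjusted p = 0.0442, and adjusted p = 0.368 with an estimated correlation). Cst7 missed the threshold over the list alone without Erg fl/fl replicate 1 (0.0669). The list was not called with fry (adjusted p = 0.264), the 25th percentile filter (0.141) or array weights (0.0844), nor without Erg fl/fl replicate 1 (adjusted p = 0.197), Erg fl/fl replicate 2 (0.0514), Erg -/- replicate 1 (0.0942) or Erg -/- replicate 3 (0.124).

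All 11 measured erythroid genes had positive differences in Erg -/- MPPs too, with a mean of 0.339 (adjusted p = 0.0016, and adjusted p = 0.218 with an estimated correlation), led by Alas2, the first enzyme of heme synthesis in red cells, at 0.63 and the anion exchanger gene Slc4a1 at 0.76 log2 units, and 0 of the 11 passed over all genes or adjusted over the list alone. The erythroid list was not called with fry (adjusted p = 0.193) or without Erg -/- replicate 2 (mean 0.162, adjusted p = 0.14). The lymphoid transcription factor gene Ebf1 stood at -1.23 log2 units (adjusted p = 0.152 over all genes) and fell when adjusted over the early lymphoid list alone, as did the cytokine subunit gene Il12a at -1.12, though with 1 array left out Il12a passed only without Erg -/- replicate 3 (otherwise up to 0.101). The other 18 lists did not pass, with adjusted p of 0.123 or more, and the interferon-response list was among them (mean 0.219, adjusted p = 0.214). Median, mean and camera direction differed in sign for 1 of them.

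**Figure D3:**
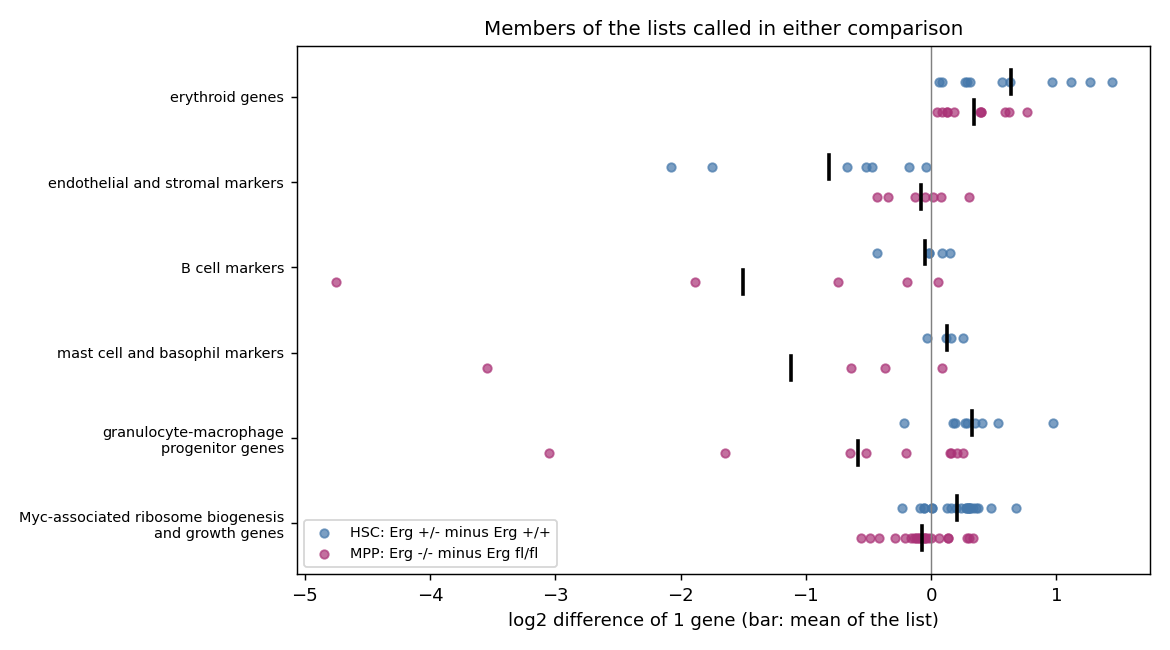
Log2 differences (horizontal axis) of the measured members of 6 lists called in either comparison (vertical axis), with a point per gene and a black bar for the mean of the list. Erythroid genes lie right of 0 in both comparisons, with means of 0.637 in HSCs and 0.339 in MPPs, and Vpreb1 lies farthest left at -4.75 in MPPs.

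The third comparison set the MPP effect against the HSC effect. The fall of Igll1 and of Ifitm1 in MPPs was larger than their difference in HSCs, by -2.03 and -1.75 log2 units (limma, SE 0.244 and 0.219, adjusted p = 0.0157 for both), as their differences in HSCs were 0.15 and 0.09. The 2 effects also differ in allele dose, cell type, pIpC treatment and the use of Mx1-Cre. AW112010 and Cracd, both with adjusted p = 0.0554, and Mcpt8, with adjusted p = 0.0877, did not pass, and 387 genes had an unadjusted p under 0.05, where 499 would be expected by chance. Both calls were lost in 7 of the 12 cases of leaving out 1 array, with adjusted p up to 0.0777: those of Erg +/+ HSC replicates 2 and 3, Erg +/- HSC replicates 1 and 3, Erg fl/fl MPP replicate 1, and Erg -/- MPP replicates 1 and 2, each of which left 0 genes called. They were also lost with the replicate block (adjusted p = 0.0984 and 0.115) and without the arrays of lowest weight (0.0665 and 0.0922).

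By list, the MPP effect lay below the HSC effect for B cell markers (adjusted p = 3.9e-05), granulocyte-macrophage progenitor genes (0.000301), mast cell and basophil markers (0.00066), Myc-associated genes (0.00312) and HSC-associated genes (0.00623), and above it for endothelial and stromal markers (0.00066). With an estimated correlation 0 of these 6 lists passed, with adjusted p = 0.475 for the Myc-associated genes and 0.0629 for the other lists. With fry the granulocyte-macrophage progenitor list (adjusted p = 0.0782) and the Myc-associated genes (0.405) did not pass. The Myc-associated genes also missed the threshold without Erg fl/fl MPP replicate 1 or Erg -/- MPP replicate 1 (adjusted p = 0.221 and 0.0523), the former taking their mean from -0.282 to -0.1745, and the HSC-associated genes without Erg +/+ HSC replicate 2 (0.0525). Of the 6 measured HSC-associated genes 4 had negative and 2 positive differences of effects, and Ifitm1, at -1.752 against a list mean of -0.463, was the 1 called over all genes.

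Across the 9984 genes the HSC and MPP effects, which share no arrays, correlated weakly (Pearson r = 0.135, Spearman rho = 0.133), where genes are not independent replicates. With 1 array left out in turn, Pearson r ranged from 0.08437 to 0.1475. No called gene was shared. Of genes at an unadjusted p under 0.05 in both, 13 were higher in both, against 3.31 expected of independent lists (Fisher's exact test, two-sided, p = 2.52e-05), and 30 were lower in both, against 12.8 (p = 1.38e-05). At an unadjusted p under 0.01 in both, 3 were higher, against 0.114 (Fisher's exact test, two-sided, p = 0.000186), and 2 lower, against 0.781 (p = 0.184), so the agreement among lower genes did not pass there. At the first threshold opposite directions were shared by 8 and 5 genes, against 9.76 and 4.34 (Fisher's exact test, two-sided, p = 0.74 and 0.624). Without Erg +/+ HSC replicate 1 and Erg fl/fl MPP replicate 1, 28 genes agreed in direction at that threshold, in place of 43. Deviations of these 2 arrays from their group means correlated at 0.104. Whether this contributes to the agreement was not tested. Fisher's exact test counts genes as independent, and both comparisons take the spread of a gene from 1 model, so the p-values of the overlaps are descriptive.

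The control groups differed more. In MPP controls the basophil protease gene Mcpt8 was 17.5-fold higher than in HSC controls, Vpreb1 8.02-fold, Flt3 5.94-fold, Serpinb1a 5.48-fold and Igll1 5.25-fold. Mmrn1, which encodes multimerin, was 19.8-fold lower, Eng, which encodes endoglin, 12.2-fold, Tgm2, a transglutaminase gene, 10.4-fold, Hacd4 9.1-fold and Chad 8.58-fold. By limma 128 genes passed, 65 higher and 63 lower, and 2226 had an unadjusted p under 0.05, with a median shift of all genes of 0.122 log2 units. Groups did not overlap for 27% of genes, where chance gives 10%, against 10.4% in the HSC and 10.5% in the MPP comparison. This contrast also differs in pIpC treatment and in the floxed allele, and 47 genes were called without Erg fl/fl replicate 2 and 48 without Erg fl/fl replicate 3. Vpreb1 missed the threshold without Erg +/+ replicate 2 or 3 or Erg fl/fl replicate 2 or 3 (adjusted p from 0.0579 to 0.106), and with only the control arrays (0.0675). Serpinb1a and Chad missed it without the arrays of lowest weight (0.0886 and 0.0614).

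All 6 measured HSC-associated genes were lower in MPP controls when adjusted over the list alone, 4 of them over all genes (Mmrn1, Tgm2, Nupr1 and Ifitm1; list adjusted p = 5.26e-14, and adjusted p = 0.000857 with an estimated correlation). B cell markers, granulocyte-macrophage progenitor genes, G2 and M phase genes, mast cell and basophil markers and early lymphoid genes were higher as groups, and interferon-response genes and endothelial and stromal markers lower, with adjusted p from 0.00212 to 0.0247. These 7 calls were lost with an estimated correlation, with adjusted p from 0.107 to 0.176. Without Erg fl/fl replicate 1 the early lymphoid, granulocyte-macrophage progenitor and mast cell and basophil lists also missed the threshold (adjusted p = 0.0747, 0.065 and 0.065), without Erg +/+ replicate 2 the early lymphoid list (0.0773), and without Erg +/+ replicate 3 the G2 and M phase list (0.0639). With the 50th percentile filter the early lymphoid and interferon lists (adjusted p = 0.168 and 0.172) did not pass. Examples are the mitotic kinase gene Plk1 at 2.24, Ebf1 at 1.49 and the interferon-induced gene Ifit3 at -1.35 log2 units, the last of which did not pass over all genes (adjusted p = 0.0729), and with 1 array left out Plk1 passed only without Erg +/+ replicate 1 (otherwise up to 0.122). Ebf1 and Plk1 also missed the threshold without the arrays of lowest weight (limma, adjusted p = 0.0608 and 0.0955).

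The Erg allele was made in embryonic stem cells, so genes beside Erg were compared with genes elsewhere. Within 20 Mb of Erg on chromosome 16, 4 of 72 genes (5.56%) had an unadjusted p under 0.05 in HSCs, against 6.33% of other genes (Fisher's exact test, two-sided, odds ratio 0.871, 95% interval 0.23 to 2.35, p = 1). In MPPs 4 of 72 did, against 4.81% (Fisher's exact test, two-sided, odds ratio 1.17, 95% interval 0.307 to 3.14, p = 0.778). Neither share differed detectably, and the intervals are wide. Sequence flanking the allele could differ between Erg +/- and Erg +/+ mice, but both MPP groups derive from the floxed allele and carry it. The MPP test therefore could not show an effect of that sequence.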

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

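The tests of other splits of the samples were fixed before their results were seen, and the other tests in this part were chosen, and some of their bounds revised, only after the patterns were seen. Differences between the HSC and the MPP effect brought up Igll1, with an MPP effect minus HSC effect of -2.035 log2 units, Ifitm1 with -1.752, and 6 lists. Their mean differences were -1.46 for B cell markers, -1.24 for mast cell and basophil markers, -0.917 for granulocyte-macrophage progenitor genes, -0.463 for HSC-associated genes, -0.282 for Myc-associated genes and 0.736 for endothelial and stromal markers. Of 100 drawn splits within the HSC and within the MPP arrays, the real one included, 9 gave at least the 2 genes of the real split, up to 8, so chance is not excluded for that count. For the 6 lists only 1 of the 100, the real one, gave as many, as counted by camera with its preset correlation, and the highest other gave 5. That count met the bound of a share under 0.05. It was 1 of several counts tested on splits, with no correction for their number. With an estimated correlation 0 of the 6 lists passed (adjusted p from 0.0629 to 0.475), and with 1 array left out the count went down to 5, so the lists themselves are not settled by this.

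The 6 arrays of a comparison of 3 against 3 make 10 splits, too few for a share under 0.05. The real HSC split gave 2 genes and 3 lists, as many as the highest of the other splits (2 genes and 3 lists), with 3 and 2 of the 10 splits reaching these counts. The real MPP split gave 8 genes and 4 lists, with 0 and 2 as the highest of the others, and that of the controls 128 genes and 8 lists, with 1 and 4, each count being reached by 1 split.

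For the fall of 8 genes in Erg -/- MPPs, a larger share of HSC-like cells in the Erg -/- gate would raise the 6 HSC-associated genes toward their HSC level, but their mean change was -0.296 (95% interval -0.463 to -0.129; 0.996 would be 0.5 of the gap), and -0.023 (95% interval -0.234 to 0.189) without Ifitm1. By gene, 5 of the 8 (AW112010, Ifitm1, Fxyd5, Vpreb1 and Nkg7) lay below control HSCs with intervals below 0, which no mixture of the 2 control populations gives, but Igll1 at 0.509, Mcpt8 at 0.584 and Serpinb1a at -0.0772 log2 units from control HSCs did not, so for these 3 this comparison cannot tell. No pIpC is recorded for the control HSCs, whereas both MPP groups received it. Levels in HSCs exposed to pIpC are unknown, so neither comparison covers an admixture of such cells. For a weaker interferon response, the interferon list (7 of 32 genes measured) had a mean of 0.219 (95% interval -0.175 to 0.613), where 0.5 of the fall of Ifitm1 is -0.831. That list was lower in MPP controls than in control HSCs, with a mean of -0.806. It thus showed no raised response in the MPP controls that could weaken, and it cannot decide this explanation. Loss of the Flt3-expressing cells is argued against by Flt3, at 0.522 (95% interval -0.0201 to 1.06) where 0.5 of its gap between the controls is -1.28. Loss of a small share of B-lineage or basophil-primed cells and lower expression per cell both stay open as hypotheses, untested in bulk RNA. In either case an effect of Mx1-Cre, absent from the Erg fl/fl mice, cannot be told apart from an effect of Erg loss.

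For the lower endothelial and stromal list in Erg +/- HSCs, endothelial cells in the Erg +/+ sorts cannot be told apart from lower expression, since Plvap, Kdr, Mmrn2 and Sox7, with a mean change of 0.00705 (95% interval -0.248 to 0.263), lie below the median of all values, where they decide little. For stromal cells, a second list, written after the result of the first and before its own values were seen (13 of 32 genes measured), had a mean of -0.265 (95% interval -0.576 to 0.0461; unadjusted p = 0.0301 by camera in limma). It leaves stromal cells open, with Serping1 at -1.73 and Mgp at -0.90 as its lowest members, but without Erg +/+ replicate 1 Serping1 was at -1.07, Mgp at -0.71 and the mean at -0.116, and the Lineage-negative, c-Kit-positive gate should remove them. If they were the single source, Sparc should follow Cxcl12, which was 9.09 in Erg +/+ replicate 1 and 6.08 and 7.03 in replicates 2 and 3, but Sparc in the latter pair lay 1.68 and 1.1 log2 units above the level its Cxcl12 gives, against 1.33 for 2 SD, so this is open as well for replicate 3. A lower expression in Erg +/- HSCs themselves, the effect of genotype, also stays open and was not tested.

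Outside the named genes, the unnamed probe set 10338545 was lower in Erg +/- HSCs by -4.423 log2 units (SE 0.468, limma adjusted p = 0.0238 over all probe sets), at 8.06 ± 0.71 in Erg +/+ HSCs and 3.64 ± 0.584 in Erg +/- HSCs (SD, n = 3 each). Between the control groups 19 unnamed probe sets were called, 3 higher and 16 lower in MPPs. The annotation lists none of these probe sets, so whether they measure transcripts or are array controls is not known.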

How the results depend on the processing

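Leaving out the 2 arrays of lowest weight was chosen after seeing the data, and the other settings were fixed before. Directions held for all but 1 of the named genes outside the cases with 1 array left out: across alternatives 1727 results of named genes stayed on their side of the threshold, 33 lost and 17 gained a call, and for lists 202 stayed and 35 lost it. Most named genes were not called in the main fit, so the 1727 are mostly uncalled genes that stayed uncalled. They say little about how firm the calls are. The lists counted here were all called in the main fit. Replicate numbers did not pair the samples: deviations of same-numbered arrays of a population correlated at -0.0852 to 0.0862, with 0 of 6 pairs over 0.1, and those across populations at -0.0402 to 0.104, with 1 of 12 over 0.1. With the replicate block, which costs residual degrees of freedom, 0 genes were called in HSCs (633 at an unadjusted p under 0.05) and 1 for the difference, with 0 shared. Other counts moved by less than 1.5 times with the block, but the odds ratios near Erg moved to 0.422 in HSCs and 2.11 in MPPs. In HSCs the count was 7 with the 25th percentile filter, 5 with trend and robust moderation, and 0 with the mean of probe sets, without the 2 arrays or with only the arrays compared (627, 601 and 475 unadjusted), the last pair with fewer residual degrees of freedom. Without the 2 arrays the counts were 4 in MPPs, 1 for the difference and 61 for the controls, of which 36 are among the 128, 28 genes overlapped in direction in place of 43, and Vpreb1 in HSCs turned to 0.3632. Trend and robust moderation gave 4 for the difference. The controls gave 61 with only the arrays compared and 60 of all probe sets, 19 higher and 41 lower against 65 and 63. Lists called in MPPs were 2 with either filter, lists of the controls 4 with the 50th percentile filter, and with an estimated correlation 1 in HSCs, 0 in MPPs, 0 for the difference and 1 for the controls. With fry they were 2, 3, 4 and 12. The filters also removed list members, and lists left with fewer than 4 were not tested. Part of the drop in lists with the filters is therefore lists no longer tested, not calls that failed. The overlap was 27 with the 50th percentile filter and 5 at p under 0.01. Odds ratios near Erg crossed 1 at 0.989 (MPPs, 10 Mb), 1.01 (HSCs, 40 Mb) and 0.941 (MPPs, 40 Mb). Apart from the residual degrees of freedom and the untested lists named, the cause was not tested. With 1 array left out in turn, genes called ranged from 1 to 8 in HSCs, 5 to 7 in MPPs, 0 to 3 for the difference and 47 to 150 for the controls, lists from 2 to 4, 3 to 4, 5 to 7 and 5 to 9, the overlap from 29 to 55, and the odds ratio from 0.374 to 1.15 in HSCs and 0.7 to 1.2 in MPPs. Directions turned then for Vpreb1 in HSCs (-0.8798 to 0.3632), Mnt in HSCs (-0.04194 to 0.1872) and Mmp9 in MPPs (-0.06394 to 0.3112), none of them called. Values near the low end of the arrays are compressed by background, which limits folds of dim genes such as Mcpt8, at 4.377 in control HSCs.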

Other observations

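The test of the axis between the populations was chosen, and its bounds set, only after the arrays had been seen. In Erg -/- MPPs 5 of the 5 measured G2 and M phase genes had negative differences, with Top2a, which encodes a DNA topoisomerase of dividing cells, at -1.43 log2 units, and the list did not pass (camera, adjusted p = 0.123). Etv5 had a positive difference in both comparisons, 0.70 log2 units in Erg +/- HSCs and 0.90 in Erg -/- MPPs, passing only when adjusted over the list alone (adjusted p = 0.0147 and 0.00431), and in HSCs not without Erg +/+ replicate 3 or Erg +/- replicate 3. In MPPs Mmrn1, an HSC-associated and megakaryocyte gene, stood at -0.79 log2 units and likewise passed only within its lists, in the megakaryocyte list not without Erg fl/fl replicate 3 or Erg -/- replicate 2 or 3 (0.055 to 0.0942).

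Arrays of Erg +/- HSCs lay between those of Erg +/+ HSCs and MPPs on the first principal component, which holds 27.63% of the variance. On an axis from Erg +/+ HSCs to MPP controls fitted without the Erg +/- arrays and with 1 Erg +/+ array held out, Erg +/- arrays lay at 0.352 to 0.474 of the way and held-out Erg +/+ arrays at 0.261 to 0.331, and in 9 of 9 pairs the Erg +/- array was nearer the MPPs. This restates the order already seen in the same arrays, so a shift of Erg +/- HSCs toward the MPP profile stays open, and held-out MPP controls lay at 0.634 for replicate 1, the array of lowest weight (0.667), and at 0.872 and 0.881 for replicates 2 and 3. Erg -/- MPP arrays lay within that range, at 0.693 to 0.791, and were nearer the HSCs than the held-out control in 6 of 9 pairs. A different spread of values between arrays is argued against, since 9 of 9 pairs kept that order after all arrays were given the same distribution. Of the 2 genes called in Erg +/- HSCs, Sparc at -2.08 log2 units had the sign of its difference in the MPP controls (-1.40) and Cracd at 1.62 the opposite one (-1.46). The lists called between the controls were mixed too. Means had opposite signs in Erg +/- HSCs and MPP controls for HSC-associated genes (0.167 and -1.99), early lymphoid genes (-0.176 and 0.829) and B cell markers (-0.0449 and 1.41). Flt3 also had opposite signs (-1.33 and 2.57). The other lists called between the controls had the same sign in both. A difference in sort purity or handling between genotypes was not tested.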
